A study of Mus musculus with 6 samples.

How the data were processed

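RNA was measured in 6 libraries of mature brown fat from mice on a C57BL/6 background, 3 labelled wild type and 3 labelled Phospho1 knockout, each a pool of 3 mice aged 6 weeks. Per the labels' protocols, minced tissue was digested with collagenase, the floating adipocyte layer was collected after a short spin, and mRNA libraries were made with a KAPA kit. The authors deposited 1 file of raw counts per library, whole numbers of reads per Ensembl gene with no normalization, over the same 37620 gene identifiers in the same order. STAR 2.5.4b and the mouse genome build mm9 are named in the submitters' processing notes. The program that counted the reads, its strand setting, the annotation release and the handling of reads with several matches are not given in the sources used here. Reads from overlapping genes on opposite strands, and from near-identical copies of a gene, therefore cannot be told apart in these counts.

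Library totals ranged from 10576800 to 14239307 counts; each library's total stands with the results. Group and replicate number came from the labels. No pair of libraries held identical values. Gene symbols, transcript lengths and GC content were taken by Ensembl identifier from GENCODE release M21 on GRCm38. Of the 37620 identifiers, 32897 matched both a symbol and a transcript length, and the rest held 0.178% of all counts. Because the files were made on mm9, no coordinates are printed, and positions served only to say within GRCm38 which genes lie near Phospho1. Of the tested genes, 98.3% had a transcript length.

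Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), leaving 12068 genes. Library sizes were scaled with TMM, dispersions were estimated with the robust option, and the groups were compared with a two-sided robust quasi-likelihood F test (the newer of edgeR's quasi-likelihood methods). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM on TMM-scaled library sizes, computed here from the deposited counts and given as mean ± SD. Each library was 1 replicate, so the spread between libraries is that between pools of mice.

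Of 42 gene lists fixed before the data were examined, the 40 with at least 5 tested members other than the sex-linked check list were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and the rotation test fry were run beside it, each adjusted over the 40 lists. Unlike camera, fry tests the members of a list against no change and not against other genes. Genes named in the text were also fixed by rule. They are Phospho1; the 10 genes with the largest log2 fold change in each direction among those past the threshold, with a mean of at least 1 CPM and no overlap between the groups, skipping genes with predicted-gene names (Gm, Rik, LOC) and pseudogenes; the 5 with the smallest p in each direction under the same conditions; up to 4 members with the smallest p in each described list; and Ucp1, Ppargc1a, Dio2, Cidea and Prdm16. B230206L02Rik, Abi3, Gngt2, Acsf2, Phb, Mrpl27, Acta1, Ckm, Myh4, Vldlr, Clock, Dusp1, Jund, Hsph1, Postn, Ddx3y and 3 pseudogenes were singled out after their values were seen. One gene that the rule names is not reported here. The share of genes past the threshold within 10 Mb of Phospho1 was compared with that of other genes by a two-sided Fisher's exact test.

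Alternatives fixed before the data were examined were RLE and upper-quartile scaling, total counts only, DESeq2 1.42.0 with its own filter in place of filterByExpr, limma-voom, edgeR's legacy quasi-likelihood method, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, and a 5 Mb window around Phospho1. Alternatives for several strand columns or for normalized values did not apply, because each file held 1 column of raw counts. After the data were seen, offsets for transcript length and GC content were added: in each library the log2 ratio of each gene to its mean over libraries (prior count 2) was fitted on log2 length of the longest transcript and on GC by smooth terms of basis size 6 (mgcv 1.9.3), and the fitted trend entered the edgeR model as an offset. The same was done with length alone, with GC alone and with the median transcript length. Each library's length slope as a covariate and the removal of mitochondrial genome genes were also added then. To place pseudogenes, annotated pseudogene transcripts were matched to protein-coding transcripts with BLAST 2.17.0 (e-value 1e-30), keeping best matches of at least 85% identity.

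The scripts were tested on simulated counts drawn for this comparison from the libraries' own means, sizes and dispersion. Without a length trend, 25% of genes changed 2-fold and 95% of genes changed 4-fold were recovered among 11855 genes tested, with 2 false calls among 122. With the libraries' own length slopes added, 205 of 343 calls among 11861 genes were false, against 7 of 144 with length and GC offsets. Changes due to the added slopes counted as false by design, and the offsets fit trends of that kind. These numbers therefore do not tell whether the real trend comes from single libraries or from genotype. Changes were planted only in genes with higher total counts, so recovery of genes with few counts was not measured. A list planted with a 2-fold change was found by camera (adjusted p = 2.6e-20, and adjusted p = 0.017 with an estimated correlation), and 0 other lists were called. Genes were drawn independently and without a length trend there, while members of the real lists vary together (estimated correlation 0.56 for the respiratory chain list). That simulation therefore does not measure how often camera calls lists falsely in these libraries.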

Results

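Gene expression was measured by RNA sequencing in mature brown fat cells, the heat-producing fat cells that float after collagenase digestion of the tissue. The series compared mice labelled wild type with mice labelled as knockouts of Phospho1, a phosphatase of phosphocholine and phosphoethanolamine. The comparison asks which transcripts differ between brown fat of mice with these labels. Each group had 3 libraries, and each library pooled 3 mice aged 6 weeks. The wild-type libraries 1, 2 and 3 held 14239307, 12826639 and 12132987 counts, and the knockout-labelled libraries 1, 2 and 3 held 10576800, 13750632 and 12244077. Genes of the mitochondrial genome took 40.7%, 39.3% and 54.3% of the counts in the wild-type libraries and 39.1%, 54.3% and 56.5% in the knockout-labelled libraries.

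Counts of Phospho1 itself (ENSMUSG00000050860, chromosome 11) did not fall in the libraries labelled knockout. The wild-type libraries held 13, 5 and 5 counts and the knockout-labelled libraries 18, 15 and 17, or 0.508 ± 0.202 and 1.52 ± 0.26 CPM (SD, n = 3 each). The log2 fold change was 1.53 (SE 0.459) and did not pass the threshold (edgeR adjusted p = 0.056). In the GRCm38 annotation, 1818 of the 2029 exonic bases of Phospho1 (89.6%) also lie in exons of Zfp652 on the same strand, and 1708 of them (84.2%) in exons of Abi3 on the opposite strand. Without the counting rules these few counts check the labels little, and the labels do not say how the allele was made. Because these counts cannot settle whether the labels hold, every direction below is that of the libraries labelled knockout.

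In those libraries, the thermogenic regulator Dio2, the hormone gene Lep and the lipid-synthesis enzyme Scd1 were lower, while Ucp1, the uncoupling protein that makes brown fat produce heat, did not pass the threshold. Dio2, which activates thyroid hormone, had 43.4 ± 26.2 CPM in wild type and 10.3 ± 2.7 CPM in the knockout-labelled libraries, a log2 fold change of -2.08 (SE 0.39, edgeR adjusted p = 0.018). Lep, the hormone leptin, had 66.4 ± 26.5 and 22.8 ± 8.1 CPM, a log2 fold change of -1.54 (SE 0.34, adjusted p = 0.023). Scd1, the delta-9 fatty acid desaturase, had 10101 ± 4296 and 3280 ± 626 CPM, a log2 fold change of -1.62 (SE 0.35, adjusted p = 0.022). Ucp1 had 2664 ± 545 and 4196 ± 588 CPM, a log2 fold change of 0.66 (SE 0.26, adjusted p = 0.113). With offsets for transcript length and GC content, described further on and chosen after seeing the data, Dio2, Lep and Scd1 were at -1.29, -1.52 and -1.16 (adjusted p = 0.079, 0.062 and 0.064). Ucp1 was at 0.44 in that fit (adjusted p = 0.166).

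**Figure D1:**
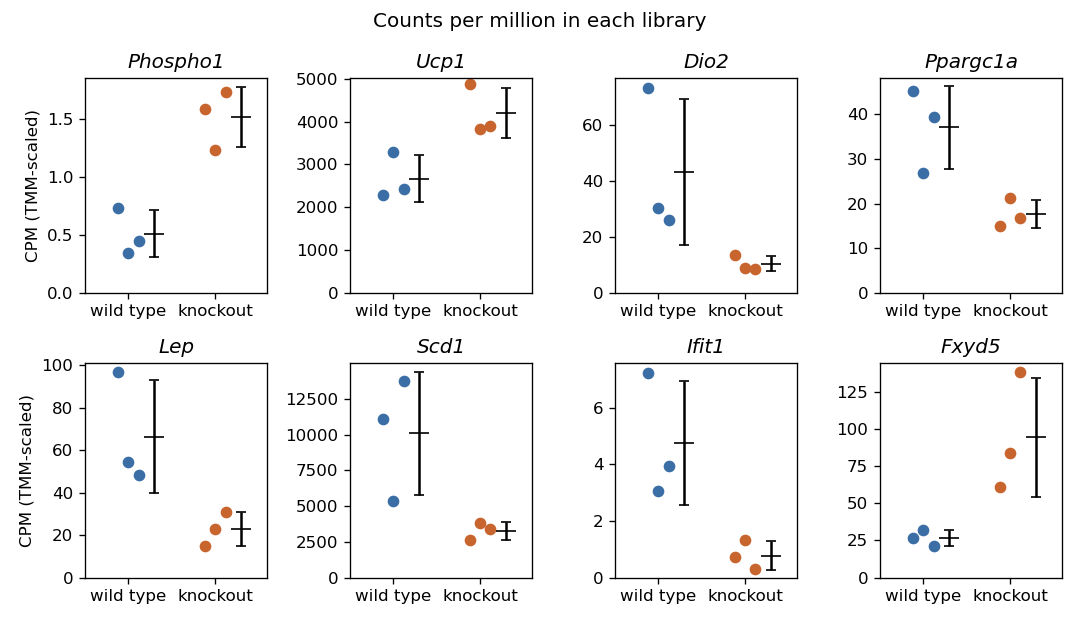
TMM-scaled CPM (vertical axes, from 0) of 8 genes in the 3 wild-type (blue) and 3 knockout-labelled (orange) libraries; each dot is 1 library, and the black mark and bars give the mean and SD. Dio2, Ppargc1a, Lep, Scd1 and Ifit1 are lower and Fxyd5 is higher in all 3 knockout-labelled libraries. Phospho1 and Ucp1 are also higher in all 3 but do not pass the threshold (adjusted p = 0.056 and 0.113).

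The genes ranked here and below leave out those with predicted-gene names (Gm, Rik, LOC) and pseudogenes, some of which rose more. Among those that rose most, Ackr1, an atypical chemokine receptor of venules, had a log2 fold change of 2.30 (SE 0.49, adjusted p = 0.022) and Gprc5a, an orphan receptor, one of 2.11 (SE 0.44, adjusted p = 0.020). Fxyd5, a regulator of the sodium pump, rose from 26.9 ± 5.5 to 94.6 ± 39.9 CPM, a log2 fold change of 1.81 (SE 0.31, adjusted p = 0.016). Mall, Vwa1, Plpp1 and Tnfaip8l1 had the other smallest p-values among the ranked genes that rose, with log2 fold changes of 1.80, 1.61, 1.35 and 1.65. BC018473, Ngfr, Dusp2, Smim3, Ly6c2 and Hba-a1 completed the largest ranked increases, from 2.48 for BC018473 to 1.80 for Smim3. Ly6c2 and the globin gene Hba-a1 have near-identical neighbours, so their single values are uncertain.

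The largest ranked decreases were in Mybpc2, Zfp820, Zfp759 and Chml, with log2 fold changes of -3.997, -3.90, -3.84 and -3.81 (SE 0.93, 0.54, 0.51 and 0.71). Their means in the knockout-labelled libraries were 0.148, 0.120, 0.263 and 0.141 CPM, near the floor, so the sizes of these decreases are imprecise. Zfp820 and Zfp759 belong to the large family of KRAB zinc-finger genes, whose members share sequence, and their values are uncertain for that reason. Lpar4, B3galt2, Kif13b, Dennd4c, Arap2 and Slc16a12 followed, from -2.94 for Lpar4 to -2.64 for Slc16a12. Kdm7a, a histone demethylase, Dmtf1, a cyclin D-binding transcription factor, and D3Ertd751e had among the smallest p-values, with log2 fold changes of -2.36, -2.16 and -1.78 (edgeR adjusted p = 0.016 for each). Mybpc2 encodes a myosin-binding protein of fast skeletal muscle and held 13, 14 and 69 counts in the wild-type libraries, the highest in wild type 3, where muscle markers took 0.361% of nuclear counts against at most 0.0327% in the other libraries. Without wild type 3 its log2 fold change was -2.44 (adjusted p = 0.066).

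In all, 197 genes were higher and 908 lower in the knockout-labelled libraries among 12068 tested (edgeR quasi-likelihood test, adjusted p under 0.05), and 1003 of these 1105 genes changed at least 2-fold. The split depended on scaling: 17.8% of calls were higher with TMM and 2.05% (29 higher, 1389 lower) with total counts alone, which moved the median log2 fold change of all genes from 0.03 to -0.23. The groups did not overlap for 35.4% of tested genes, against 10% by chance for 3 against 3. Genes vary together, with 56.9% of the variance on the first principal component, so that share is a description and not a test of the groups. The counts rested on single libraries: 0 genes passed without wild type 1, although 2251 had an unadjusted p under 0.05, and 2 higher and 0 lower genes passed without knockout 3 (2672 at an unadjusted p under 0.05). Without wild type 3, 31 were higher and 366 lower; without knockout 2, 47 and 258; without wild type 2, 688 and 1383; and without knockout 1, 298 and 994.

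Genes with long transcripts were lower and genes with short transcripts higher in the knockout-labelled libraries. The median log2 fold change went from 0.59 among the 1191 genes of the shortest length decile (median 883 bases) to -0.78 among the 1187 of the longest (median 8054 bases), and Spearman's rho across genes, which are not independent replicates, was -0.58 with length and 0.39 with GC content. Lower calls made up 24.8% of the longest decile and 0.168% of the shortest. For each library, the log2 ratio of each gene to its mean over the 6 libraries was regressed on log2 length, so the slopes are relative to the other libraries. They were 0.306, -0.025 and 0.2996 in the wild-type libraries and -0.238, -0.093 and -0.249 in the knockout-labelled ones, so wild type 2 lay nearer to the latter. The mean slopes differed by -0.387 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). With offsets for length and GC, chosen after seeing the data, 1 gene was higher and 0 were lower (edgeR, 2769 at an unadjusted p under 0.05), although 853 of the 1105 calls kept their direction at an unadjusted p under 0.05. B230206L02Rik was that gene, so no other gene named in the text passed with them. The second smallest adjusted p in that fit was 0.062, so the count hangs on the threshold. At an adjusted p under 0.1 in edgeR, 555 genes were higher and 483 lower with the offsets, against 748 and 1630 without. These offsets use each gene's longest transcript. With the median transcript in its place, 105 genes were higher and 170 lower, so the count of calls depended on the length used. With the offsets on the longest transcript, Kdm7a moved from -2.36 to -1.18 and B3galt2 from -2.82 to -1.60, while Zfp759 was at -3.35 and Fxyd5 at 1.68. Each gene group is therefore given with its value under these offsets.

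**Figure D2:**
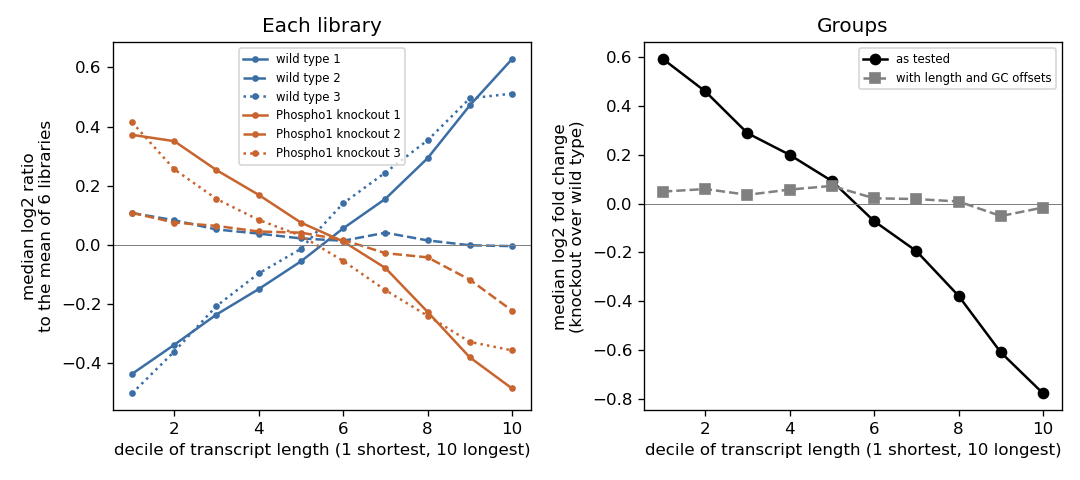
Left, median log2 ratio to the mean of the 6 libraries (vertical) in deciles of transcript length (horizontal, 1 shortest) for each wild-type (blue) and knockout-labelled (orange) library. Right, median log2 fold change between groups in the same deciles as tested (black circles), from 0.59 to -0.78, and with length and GC offsets (grey squares), where it stays between -0.05 and 0.07.

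Among 25 tested genes of the brown thermogenic list, 4 fell, 1 rose and 20 did not pass, and the counts adjusted over the list alone were also 4 and 1. Dio2, the orphan receptor Esrrg (-1.73), the coactivator Ppargc1a (-1.07) and the brown-fat determination factor Ebf2 (-0.98) fell, and the cytochrome oxidase subunit Cox7a1 rose (1.02). Cidea, a lipid droplet protein, had a log2 fold change of 0.47 (adjusted p = 0.246), and Prdm16, a brown-fat transcriptional regulator, -0.51 (adjusted p = 0.281). With the offsets Dio2, Esrrg, Ppargc1a, Ebf2 and Cox7a1 were at -1.29, -1.03, -0.13, -0.39 and 0.26, and the list did not differ from other genes in either fit (camera adjusted p = 0.934 and 0.772).

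Of 17 brown adipocyte transcription and secreted factors, 3 fell and 5 fell when adjusted over the list alone. Those that fell included the thyroid hormone receptor Thrb (-1.78) and Zbtb16 (-1.44). Among 19 adrenergic signalling genes 3 fell, the phosphodiesterase Pde3b (-1.45) and the transcription factors Creb1 (-1.28) and Atf2 (-0.93), and 3 adjusted over the list alone. Among 23 mitochondrial biogenesis and dynamics genes 4 fell, the fission and fusion GTPases Dnm1l (-1.65) and Opa1 (-1.51), Gabpa (-1.41) and the chaperone Hspd1 (-1.06); adjusted over the list alone, 4 fell and 2 rose. None of these 3 lists passed against other genes (camera adjusted p = 0.127, 0.172 and 0.480), and with the offsets the transcription and secreted factor list did (median -0.39, adjusted p = 0.046; adjusted p = 0.736 with an estimated correlation). In that fit Thrb and Zbtb16 were at -0.99 and -1.16, Pde3b, Creb1 and Atf2 at -0.67, -0.18 and -0.31, and Dnm1l, Opa1, Gabpa and Hspd1 at -1.10, -0.70, -0.74 and -1.14. The adrenergic and mitochondrial dynamics lists did not pass with the offsets (medians -0.098 and 0.00057, adjusted p = 0.299 and 0.446).

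Among 20 de novo lipogenesis enzymes 3 fell, the desaturases Scd1 and Scd2 (-1.15) and the elongase Elovl6 (-1.37), and 4 fell adjusted over the list alone. Among 12 adipokines and white adipocyte markers Lep fell, and 1 fell adjusted over the list alone. Of 16 core adipocyte genes 2 fell, the activin receptor-like kinase Acvr1c (-1.69) and the insulin receptor Insr (-1.64); adjusted over the list alone, 3 fell and 1 rose. These lists did not pass as tested (camera adjusted p = 0.127, 0.275 and 0.569). With the offsets the lipogenesis list (median -0.28, adjusted p = 0.012) and the white adipocyte list (median -0.94, adjusted p = 2.8e-05) did, neither with an estimated correlation (adjusted p = 0.736 for both), and Scd2, Elovl6, Acvr1c and Insr were at -0.71, -0.56, -0.58 and -0.86. The core adipocyte list did not pass with them (median -0.20, adjusted p = 0.232).

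Interferon-stimulated genes included 5 lower genes among 21 tested, and 8 adjusted over the list alone, with none higher in either count. Ifit1, an inhibitor of viral RNA translation, went from 4.75 ± 2.19 to 0.775 ± 0.506 CPM (log2 fold change -2.57, SE 0.51), and the RNA sensor Ifih1, Iigp1 and Rsad2 had log2 fold changes of -1.54, -1.34 and -1.15. With the offsets these 4 genes were at -2.45, -0.81, -0.92 and -0.72. The list did not pass as tested (camera adjusted p = 0.127) and passed with the offsets (median -0.33, adjusted p = 0.012; adjusted p = 0.736 with an estimated correlation).

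As whole lists, 5 of the 40 rose against other genes by camera with the preset correlation, with median transcript lengths from 699 bases (erythroid) to 2060 bases (antioxidant). Other splits of the 6 libraries into groups of 3 gave 4 to 11 lists past the threshold with the same test. The number of lists called therefore does not set the real groups apart, and camera p-values with the preset correlation may be far too small here. The 74 nuclear-encoded respiratory chain and ATP synthase subunits had a median log2 fold change of 0.66 (camera adjusted p = 4.8e-14; adjusted p = 0.725 with an estimated correlation), and Ndufc1 (1.09), Ndufb2 (1.09), Cox7a1 and Atp5h (0.98) passed. The 69 ribosomal proteins had a median of 0.64 (adjusted p = 4.6e-06; adjusted p = 0.725 with an estimated correlation), with Rps28 (1.22), Rps15a (1.18), Rps20 (0.94) and Rpl32 (0.93) past the threshold. The 72 mitochondrial ribosome genes had a median of 0.57 (adjusted p = 4.7e-10; adjusted p = 0.725 with an estimated correlation), with Mrpl52 (1.07) past it. Adjusted over the list alone, 0 genes of each of these 3 lists passed in edgeR, where 46, 27 and 37 had an unadjusted p under 0.05, and over all genes limma-voom called 3, 3 and 0 higher and DESeq2, run with its own filter on low counts, 22, 9 and 11. The 20 antioxidant genes had a median of 0.56 (adjusted p = 0.018; adjusted p = 0.725 with an estimated correlation) with 0 genes past the threshold in edgeR, 8 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. The 5 erythroid markers had a median of 1.42 (adjusted p = 0.001; adjusted p = 0.725 with an estimated correlation), with Hba-a1 and the haem synthesis enzyme Alas2 (1.42) past the threshold and 5 adjusted over the list alone. None of the 5 lists passed with fry either. With the offsets Ndufc1, Ndufb2, Cox7a1 and Atp5h were at 0.95, 1.61, 0.26 and 0.57, Rps28, Rps15a, Rps20 and Rpl32 at 0.93, 1.72, 1.44 and 0.36, and Mrpl52, Hba-a1 and Alas2 at 0.43, 1.09 and 1.05. The list medians were then 0.18, 0.18, 0.21, 0.19 and 0.94 in the order given, and the respiratory chain (camera adjusted p = 0.002), mitochondrial ribosome (2.8e-05) and erythroid lists (0.012) still passed, none of them with an estimated correlation (adjusted p = 0.736 for each) or with fry (adjusted p = 0.274, 0.274 and 0.279). The offsets take each gene's longest annotated transcript, 4371 bases for Ndufb2, 5179 for Rps15a and 3706 for Rps20, and they raised these genes. Where a shorter transcript is the one expressed, such values, and list results that rest on them, may be too high.

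**Figure D3:**
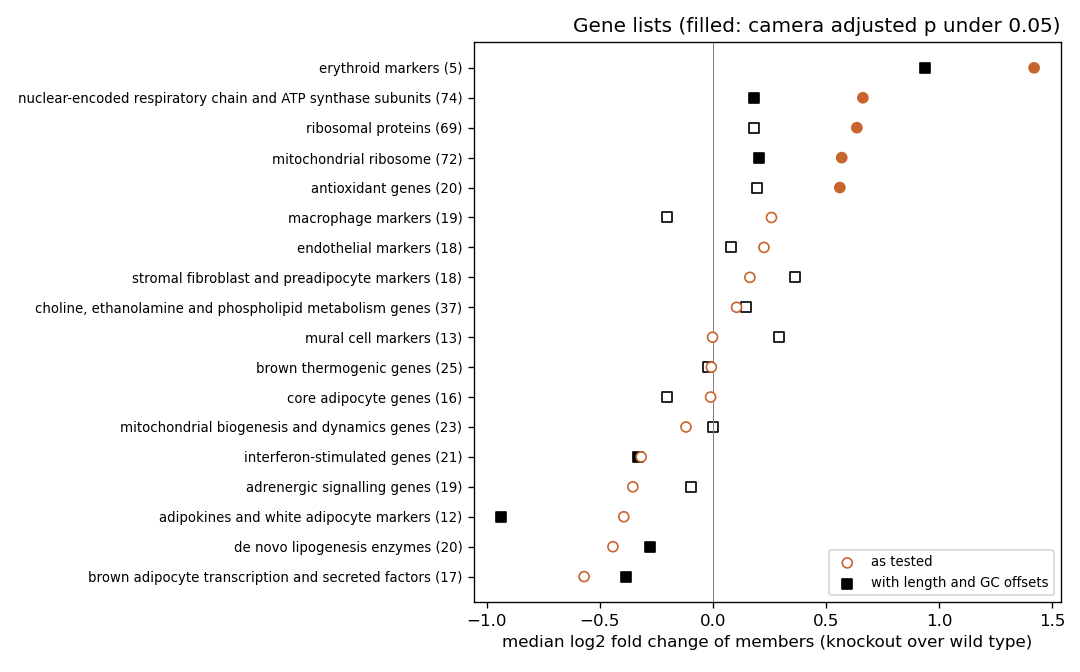
Median log2 fold change (horizontal) of the tested members of 18 gene lists (number of members in brackets), as tested (orange circles) and with length and GC offsets (black squares); filled symbols passed camera with the preset correlation. The respiratory chain list moves from 0.66 to 0.18 and the adipokine and white adipocyte list from -0.39 to -0.94.

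Genes of choline, ethanolamine and phospholipid metabolism, the pathway of the enzyme Phospho1, gave 0 calls among 37 tested genes in edgeR, DESeq2 and limma-voom and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.702; with the offsets, median 0.15, adjusted p = 0.299).

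Markers of other cell types moved in both directions. Among 18 endothelial markers Ptprb (-1.52), Flt1 (-1.24) and Tek (-1.21) fell and the lipase anchor Gpihbp1 rose (0.97), and adjusted over the list alone 5 fell and 5 rose. Of 13 mural cell markers Myl9 (1.04), Tagln (1.02) and Acta2 (0.99) rose and Abcc9 fell (-1.17); adjusted over the list alone, 4 rose and 2 fell. Ly6a (1.31) and Cd34 (0.95) rose among 18 stromal markers, with 3 higher and 1 lower adjusted over the list alone. Of 19 macrophage markers Lyz2 rose (1.43) and Cd163 fell (-2.44), with 1 higher and 2 lower adjusted over the list alone. With the offsets Ptprb, Flt1, Tek and Gpihbp1 were at -0.81, -0.68, -0.80 and 0.54, Myl9, Tagln, Acta2 and Abcc9 at 0.40, 0.59, 0.74 and -0.39, and Ly6a, Cd34, Lyz2 and Cd163 at 0.86, 1.24, 1.07 and -2.10. None of these 4 lists passed against other genes (camera adjusted p = 0.755, 0.480, 0.442 and 0.611). With the offsets their medians were 0.08, 0.29, 0.36 and -0.20 (adjusted p = 0.897, 0.299, 0.231 and 0.788), the macrophage median having been 0.26 as tested.

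In the fit without offsets, genes near Phospho1 were called about as often as others, with no difference past the threshold. Within 10 Mb of it, 22 of 219 tested genes passed the threshold (10.05%), against 1065 of 11644 others (9.15%; odds ratio 1.11, two-sided Fisher's exact p = 0.636). Without knockout 3, where 2 genes passed in all, the odds ratio was 53.6 (exact p = 0.036). The adjacent gene Gngt2, a G protein subunit, rose (1.08, adjusted p = 0.044), and Abi3 had a log2 fold change of 1.17 (adjusted p = 0.083). For Abi3 the groups overlapped, with 5.84 CPM in knockout 1 against 6.32, 6.01 and 7.36 in the wild-type libraries. Ngfr, among the largest ranked increases, lies 0.256 Mb from Phospho1 (2.04, edgeR adjusted p = 0.043, and 1.87 with the offsets). Acsf2, an acyl-CoA synthetase, fell (-1.84). With the offsets Gngt2, Abi3 and Acsf2 were at 0.68, 1.11 and -1.999. The uncharacterised transcript B230206L02Rik, which lies 1.69 Mb from Phospho1, had 26, 32 and 17 counts in wild type and 151, 153 and 155 in the knockout-labelled libraries. Its log2 fold change was 3.00 (SE 0.304, adjusted p = 0.006). Of all tested genes it was the 1 past the threshold with the length and GC offsets (2.34, adjusted p = 0.014), so the 1 call left by them lies near Phospho1. Without wild type 1 none of these genes passed the threshold.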

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

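Offsets, the slope covariate and the removal of mitochondrial genome genes were chosen after seeing the data; the other settings were fixed before. The cause was not tested for any change below except where a stricter threshold gives it. Fits with 1 library left out all held the same number of libraries but gave very different counts. Fewer libraries alone therefore do not explain those counts. Against 197 higher and 908 lower genes, total counts alone gave 29 and 1389, DESeq2 with its own filter, a change of test and filter at once (21216 genes against 12068), gave 493 and 1349, and an adjusted p of 0.01 left 1 and 0 (1 over 2-fold). Length and GC offsets gave 1 higher and 0 lower (1 over 2-fold; 1445 higher and 1324 lower at an unadjusted p under 0.05), length offsets alone 13 and 34 (47 over 2-fold), GC offsets alone 390 lower (587 over 2-fold), and offsets on the median transcript 105 and 170 (271 over 2-fold). The length slope as a covariate left 0 and 0 in edgeR (0 over 2-fold; 267 at an unadjusted p under 0.05), in a model with fewer residual degrees of freedom. The slopes also did not overlap between the groups, so that model can hardly separate the covariate from the group labels. Leaving out 1 library gave 0 to 688 higher, 0 to 1383 lower and 0 to 1711 over 2-fold genes, with 0 in edgeR without wild type 1 (2251 at an unadjusted p under 0.05). The 5 lists past the threshold became 11 with no filter, 9 with length and GC offsets, 8 with GC offsets alone or with the median transcript, and 0 with an estimated correlation or fry, and 5 to 8 with 1 library left out; they were not run with DESeq2 or limma-voom. Phospho1 stayed higher and short of the threshold in all settings, at 1.01 (median transcript offsets) to 2.02 (slope covariate), and from 1.31 to 1.92 with 1 library left out. The odds ratio for genes near Phospho1 fell below 1 with the replicate block (0.961), GC offsets (0.741) and a 5 Mb window (0.929), and ranged from 0.743 without knockout 1 to 53.6 without knockout 3 (exact p = 0.036), where 2 genes passed. With no call there was no ratio. With length and GC offsets, and at an adjusted p of 0.01, the 1 call was B230206L02Rik. It lies 1.69 Mb from Phospho1, inside the window, so the ratio was not finite and no p-value is given. Of the 93 genes followed through these settings besides Phospho1, Cidea turned to -0.13 with length and GC offsets, -0.0042 with length offsets and -0.21 with the slope covariate, and Prdm16 to 0.27 with length offsets. Acta1 and Ckm turned to 0.036 and 0.26 without wild type 3 (lowest with 1 library left out, -2.61 and -3.48), and with the slope covariate Acta1, Ckm, Myh4 and Abcc9 were at 0.57, 1.27, 0.92 and 0.12. Directions of the other followed genes held. With length and GC offsets 83 lost their call, with length offsets 72, with median transcript offsets 47 and with GC offsets 30. All calls were lost with the slope covariate, and 83 at an adjusted p of 0.01. Leaving out a library cost 84 calls without wild type 1, 82 without knockout 3, 44 without wild type 3, 43 without knockout 2, 16 without knockout 1 and 2 without wild type 2. Total counts alone cost 23, limma-voom 12, and RLE or upper-quartile scaling, the legacy method, no filter or the replicate block at most 5 each. Deviations from the group means had correlations of 0.145, -0.534 and 0.032 between libraries with the same number. With 3 libraries per group the deviations are tied to each other, so these correlations cannot decide whether the numbers pair the libraries. The replicate block gave 223 higher and 976 lower genes. Of the 10 splits of the 6 libraries into groups of 3, 1 (the real split) gave 197 higher, 908 lower and 1003 over 2-fold genes, and the highest other value was 0 for each in edgeR (1784 at an unadjusted p under 0.05). For lists, 8 splits gave 5 or more and the highest other value was 11. These 10 splits are too few for a share under 0.05. Phospho1 held 5 to 18 counts per library, which leaves a wide counting error; other effects of depth were not tested.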

Other observations

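The tests of explanations below were chosen only after the results were seen, and the rule for the slopes of single libraries was made stricter after its first outcome. Lists not described so far held few calls. Of 17 lipid uptake genes, Vldlr fell (-1.39, edgeR adjusted p = 0.017; -0.50 with length and GC offsets) and Gpihbp1 rose. Among 17 clock genes, Clock itself fell (-2.04, adjusted p = 0.016; -1.02 with length and GC offsets). Among 27 immediate-early and dissociation stress genes, Dusp1 (0.99) and Jund (0.92) rose and Hsph1 fell (-1.15); with the offsets they were at 0.68, 0.31 and -0.74. The 26 extracellular matrix genes passed camera with the offsets (median 0.41, adjusted p = 0.045; adjusted p = 0.736 with an estimated correlation), although as tested the call in that list was a decrease, Postn (-1.62; -0.64 with the offsets). Transcripts of the Y chromosome were present in all 6 libraries, and Xist held 0, 0 and 3 counts in wild type and 0, 1 and 0 in the knockout-labelled libraries. Ddx3y was lower in the latter (2842, 1613 and 1099 counts against 799, 381 and 200), at -1.59 (edgeR adjusted p = 0.036) and -0.77 with the offsets. Eif2s3y, Kdm5d and Uty, also of the sex-linked check list, held fewer unscaled counts in every knockout-labelled library than in any wild-type one. Without wild type 3 they were at -1.01, -1.12 and -1.51 (adjusted p = 0.167, 0.161 and 0.117). Vldlr, Clock, Dusp1, Jund, Hsph1, Postn and Ddx3y were chosen after their values were seen.

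Fold changes fell with transcript length. GC content alone was argued against as the source: with GC offsets, Spearman's rho between fold change and length across genes was still -0.514. Differences between single libraries, which RNA integrity or library preparation may set, stay open: the slopes spanned 0.332 within the wild-type group, through wild type 2, and 0.156 within the knockout-labelled group, against 0.387 between the group means. An effect of genotype on long transcripts stays open too, since the exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow and decides nothing.

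Pseudogene copies of 2 genes near Phospho1 were higher in the knockout-labelled libraries: Gm7666 and Gm9673, copies of Phb, had log2 fold changes of 3.73 and 4.25, and Gm6304, a copy of Mrpl27, had 3.40. The other 5 tested copies of genes within 10 Mb of Phospho1 did not pass (1.04 to -0.28), against 8 called higher of 348 copies of other genes (two-sided Fisher's exact p = 1 without the 3 copies that prompted the question). The length trend was argued against, since the lowest of the 3 was still 2.66 with length and GC offsets. Counts of the parents were not higher, with Phb and Mrpl27 at -0.36 and -0.46 as tested (edgeR adjusted p = 0.337 and 0.304). With the offsets they were at -0.80 and -1.11 (adjusted p = 0.072 and 0.062). These counts cannot decide on higher output of the parents, because any parent reads that align to the copies would be missing from them. A candidate explanation, as a hypothesis, is that sequence around the Phospho1 allele differs from the reference, so that reads of Phb and Mrpl27 align to their copies elsewhere; it stays open, as does transcription of the copies themselves, because the other copies are too few and need not carry variants.

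Skeletal muscle markers had a list median of -2.83 (18 tested genes, camera adjusted p = 0.135; -3.55 and adjusted p = 0.0033 with length and GC offsets, adjusted p = 0.741 with an estimated correlation), with 0 calls in edgeR (1 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). Muscle RNA in the wild type 3 pool is a candidate source: its share of muscle transcripts among nuclear counts was 0.361%, 11.04 times that of the next library, and Acta1, Ckm and Myh4 held 2223, 1541 and 852 counts there against at most 454, 178 and 21 in the other 5. Genotype was argued against, since without wild type 3 the list median was 0.041. The floating layer collected for these libraries would leave out whole muscle fibres, and some list members, such as Acta1, were detected in all 6 libraries.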
